A study of Mus musculus with 6 samples.

How the data were processed

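Total RNA of starved and control cells was labelled with biotin and hybridised to 6 Affymetrix mouse arrays, 3 per group. The deposited table holds log2 values, 1 per probe set and array, which the authors made with RMA in the affy package, per the submitters' processing notes; versions are not given in the sources used here. RMA corrects background, quantile normalizes the arrays and summarises the probes of a set. Quantile normalization gives all arrays nearly the same distribution, so that a shift of most transcripts in a single direction would not be visible. Array medians lay between 6.74 and 6.78. The values carry no detection calls, so a level of 5 (log2) was used as a limit for dim probe sets. Arrays have no read depth, and their number limits the precision.

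The table held 22690 probe sets with 0 missing values. 64 Affymetrix control probe sets were set aside and 22626 were tested. Gene names came from the platform annotation: 20380 probe sets named 1 gene, 691 named several and were not named here, and 1555 had no name here. Symbols were checked through Entrez identifiers against a RefSeq gene table, which changed 0 symbols; the identifiers of 29 named probe sets had no match in it. Of the 12393 genes measured, 4956 had more than 1 probe set, and each gene was represented by the probe set with the highest mean over all 6 arrays. In 125 of the genes called, another probe set was called in the opposite direction.

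Groups were taken from the sample titles. Starved and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the deposited values with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. The 39 gene lists, covering nutrient stress, lysosome, autophagy, calcineurin, metabolism, growth signalling, cell cycle, inflammation and cell type markers, were fixed before the data were examined, and 948 of their 1062 entries were measured. They were tested with camera (correlation of 0.01, and estimated) and fry, adjusted over the 39 lists. Probe sets for the 3 prime and 5 prime ends of Gapdh and Actb were compared by an exact permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

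Genes were named by a rule fixed with the lists. It took the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, without predicted or clone names. From each list it took up to 4 members past the threshold with the largest absolute change and up to 2 others of the highest level, of which the text gives a part, and it always took a fixed set of genes of calcineurin, lysosome, autophagy, stress and growth. Tfe3 of this set was not analysed here, and 1 other gene of it is not reported here.

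The fit was tested on simulated data drawn from the means and residual spreads of the 22626 probe sets for the comparison of starved with control arrays, with seeded sets of probe sets changed by known amounts. It recovered 98.5% of 67 changed by 1 (log2), 48.7% of 76 changed by 0.5 and 3.51% of 57 changed by 0.25, and 3.67% of its calls were false. Far fewer probe sets changed in the simulation, with 109 calls against 8933 in the data. Its adjusted threshold was therefore stricter, and the shares recovered at 0.5 and 0.25 do not carry over to the data.

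The alternatives fixed beforehand were a filter on dim probe sets, a second quantile normalization, centring on array medians, an intensity trend with robust moderation, no moderation, array weights, leaving out probe sets that can match several transcripts, the mean of all probe sets of a gene, adjustment over 1 probe set per gene, a minimum change of 1, a threshold of 0.01, the replicate number as a block and leaving out each array. For gene lists, the ranges over alternatives also take in fry and camera with an estimated correlation. A test of gene families by symbol was added after the data were seen. No scan dates or batches were used here, so a batch that follows the groups cannot be told apart from starvation.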

Results

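Gene expression was measured on 6 Affymetrix mouse arrays, each hybridised with biotin-labelled cRNA made from the total RNA of cultured cells of a line called PPP3R1. PPP3R1 is also the name of calcineurin B, the regulatory subunit of the calcium-dependent phosphatase calcineurin, and the labels do not say what was done to that gene in the line. 3 arrays came from cells starved for 6 h and 3 from cells kept in normal medium, called control here; the composition of the starvation medium is not given in the sources used here. The sample titles and the series design name the PPP3R1 line in normal medium as the control, whereas the growth and treatment protocols both name wild-type mouse embryonic fibroblasts. The grouping follows the titles, and this conflict applies to every difference below. The titles call the arrays biological replicates without saying whether the cultures were separate, so p-values measure the spread between these samples, and the number of arrays limits the precision. Changes are starved minus control on the log2 scale, with the standard error from limma and n = 3 per group.

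The single comparison of the design asks which transcripts changed when the cells were starved. Genes of cholesterol synthesis and of glycolysis fell, most genes for lysosomal enzymes fell by a smaller amount, and genes of mitosis and of the interferon response rose. These 5 list calls were made with a preset correlation between genes and none held with an estimated correlation (adjusted p = 0.212 for cholesterol synthesis, lysosomal enzymes and mitosis, adjusted p = 0.387 for glycolysis and adjusted p = 0.301 for interferon, each with an estimated correlation). In limma's test 8933 of 22626 probe sets passed an adjusted p of 0.05, 4589 higher and 4344 lower in starved cells. Counted over genes, 5059 of 12393 (40.8%) passed, 2574 higher and 2485 lower. Most changes were small: the median absolute change of all genes was 0.16 against a median standard error of 0.07, and 398 genes changed by at least 1 (212 higher, 186 lower). Both group means lay under 5, close to the background of these arrays, in 231 of the genes called. Arrays of the same group correlated at 0.998 across probe sets, and arrays of different groups at 0.986 to 0.988.

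Inmt, which encodes indolethylamine N-methyltransferase, had the largest change of all genes, from 12.12 ± 0.07 (SD, n = 3) in control to 5.64 ± 0.03 (SD, n = 3) in starved cells. This fall of 6.47 ± 0.06 (SE) was 88.8-fold on this scale (limma adjusted p = 2.6e-09), and it rests on 1 probe set. The next largest falls were those of Msmo1 (-3.61 ± 0.07), Cyp2f2 (-3.48 ± 0.11), the matrix metalloproteinase gene Mmp3 (-3.47 ± 0.06), Tnfrsf21 (-3.08 ± 0.11), Sqle (-2.91 ± 0.06), Idi1 (-2.88 ± 0.06), the chemokine gene Ppbp (-2.61 ± 0.07), Mmp13 (-2.58 ± 0.08) and Cpxm1 (-2.49 ± 0.07). Msmo1, Sqle and Idi1 encode enzymes of sterol synthesis. The largest rises were those of the interferon-induced genes Cxcl10 (2.77 ± 0.20), Rsad2 (2.69 ± 0.21) and Mx1 (2.46 ± 0.30), of C1qtnf3 (2.63 ± 0.11), the smooth muscle actin gene Actg2 (2.61 ± 0.13), Tmeff2 (2.41 ± 0.08), the cytokine gene Il15 (2.38 ± 0.08), Ctnnd2 (2.18 ± 0.07), the mitotic kinase gene Mastl (2.16 ± 0.12) and the kinetochore gene Ndc80 (2.11 ± 0.06). Some of these changes start or end under the level of 5 used as a limit for dim probe sets. C1qtnf3 and Ctnnd2 had control means of 3.02 and 3.27, and Tnfrsf21 and Cyp2f2 had starved means of 3.76 and 4.61. The sizes of these 4 changes are less certain.

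**Figure D1:**
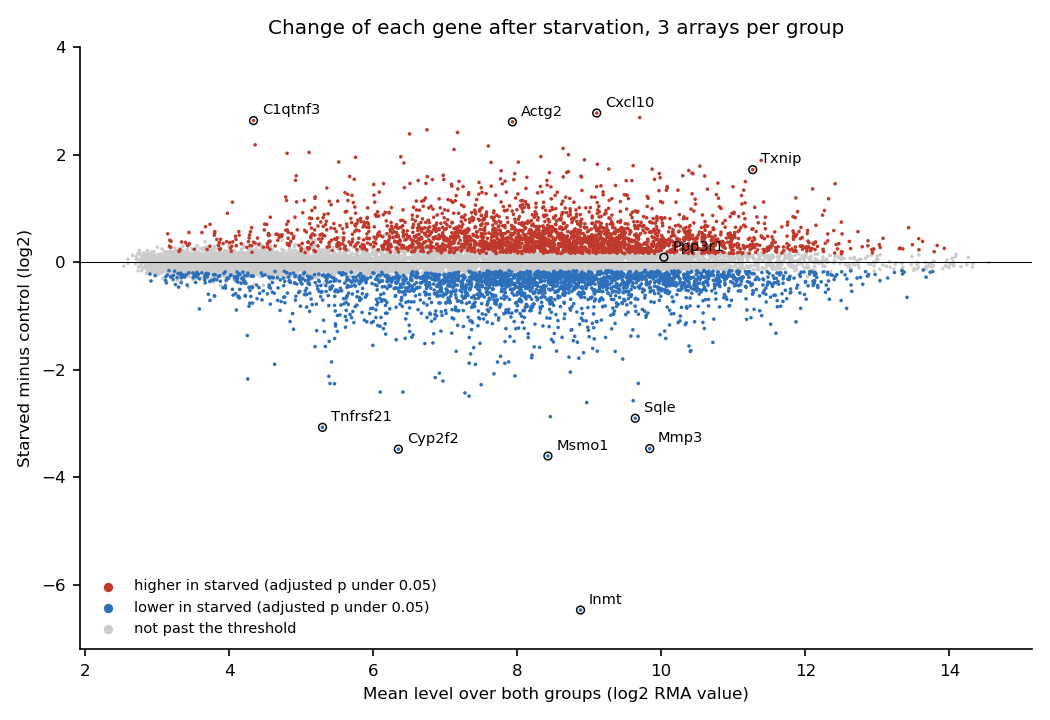
Change of each of 12393 genes (starved minus control, log2) against its mean level over both groups (log2 RMA value), with 1 point per gene, red for 2574 genes called higher, blue for 2485 called lower and grey for the rest. Inmt lies apart from all other genes at -6.47, and Ppp3r1 lies at 0.09.

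Each of 39 gene lists fixed in advance was tested with camera, a competitive test of a list against all other genes. With a preset correlation between genes 20 lists passed an adjusted p of 0.05 (9 higher and 11 lower in starved cells), and 0 passed when the correlation was estimated from these arrays (8 at an unadjusted p under 0.05). Lists with an estimated correlation below the preset 0.01 lost their call too, so this loss does not measure correlation alone. For the lysosomal membrane list the estimate was -0.014, and the unadjusted camera p was 0.0238 against 0.00150 with the preset value. Fry, which asks whether the genes of a list move on balance in a single direction and compares them with no other genes, passed 28 lists. It passed 9 that camera did not: YAP-TEAD targets and neural and glial markers in the higher direction (fry adjusted p = 0.00199 and 0.00359), with cyclin D and cell cycle inhibitors (0.00157) and NRF2 targets (0.00839). In the lower direction it passed the calcineurin list (0.00227), serum immediate early genes (0.00583), ribosome biogenesis (0.0110), the circadian clock (0.0151) and fibroblast markers (0.00199). Counts of members adjusted over the list alone are given where they differ from those adjusted over all probe sets. Ranges over the alternatives of a list include fry and camera with an estimated correlation, so their ends can come from those tests.

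Ppp3r1 itself was at 9.99 ± 0.03 (SD) in control and 10.08 ± 0.01 (SD) in starved cells, a difference of 0.09 ± 0.05 that did not pass (limma adjusted p = 0.215), and its other probe set lay near background. It passed without moderation of the spread (adjusted p = 0.0208, range over its alternatives 0.0208 to 0.898). Of 16 measured genes for calcineurin subunits and the NFAT-calcineurin response, 2 rose and 5 fell, or 3 and 5 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.550) but passed fry in the lower direction (adjusted p = 0.00227). The catalytic subunit gene Ppp3ca fell by 0.20 ± 0.05, and this call was lost without starved replicate 2 (adjusted p = 0.0577, range over its alternatives 0.000631 to 0.0577). Ppp3cb fell by 0.21 ± 0.06 in its brighter probe set while its other probe set rose by 0.61 ± 0.07, so the gene has no settled direction. The call of the brighter probe set was lost on leaving out any array but starved replicate 1 (adjusted p from 0.0507 to 0.0983), with the replicate number as a block (0.0685) and without moderation (0.0511; range over its alternatives 0.00373 to 0.0983). Adamts1 fell by 0.53 ± 0.07. Rcan1, a standard reporter of calcineurin activity, differed by 0.12 ± 0.06 without passing (adjusted p = 0.154).

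Lysosomal hydrolase genes fell: 26 of 34 were lower and 2 higher, with a median change of -0.38 (camera adjusted p = 1.38e-07, and adjusted p = 0.212 with an estimated correlation). The largest falls were in the genes of beta-glucuronidase, Gusb (-1.27 ± 0.06), and of the cathepsins Ctsa (-0.89 ± 0.06), Ctsf (-0.73 ± 0.06) and Ctsh (-0.71 ± 0.07), and Ctsd fell by 0.27 ± 0.05. Ctsl, at a control level of 13.23, differed by -0.09 ± 0.06 without passing. Of 26 genes for lysosomal membrane proteins and the proton pump, 11 fell and 1 rose, or 11 and 2 adjusted over the list alone (median -0.16, camera adjusted p = 0.00532, and adjusted p = 0.212 with an estimated correlation). They included the pump subunit genes Atp6v0b (-0.68 ± 0.06) and Atp6v1h (-0.48 ± 0.06) and the calcium channel gene Mcoln1 (-0.29 ± 0.06), while Lamp1 differed by -0.12 ± 0.06 without passing. This list lost its camera call without the probe sets that can match several transcripts (adjusted p = 0.102). Its alternatives ranged from an adjusted p of 4.81e-05 with fry to 0.212 in camera with an estimated correlation.

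Among autophagy genes more were called higher than lower. Of 33 measured, 15 rose and 4 fell, or 16 and 5 adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.0323, and adjusted p = 0.387 with an estimated correlation). The cargo receptor gene Sqstm1 rose by 0.96 ± 0.05, Rb1cc1 by 0.66 ± 0.07, Tax1bp1 by 0.61 ± 0.06 and Uvrag by 0.29 ± 0.05. Bnip3, which is also induced by hypoxia, fell by 1.12 ± 0.12, and Map1lc3b fell by 0.32 ± 0.07 in its brightest probe set but did not pass in the mean of its probe sets (-0.13, adjusted p = 0.0711, range over its alternatives 1.42e-05 to 0.158). The list lost its call without starved replicate 1 (adjusted p = 0.111), without dim probe sets (0.0920) and without probe sets that can match several transcripts (0.245), with a range over its alternatives of 0.00199 to 0.387. Of 21 genes for MiT/TFE transcription factors and regulators of the growth kinase mTORC1, 10 fell and 2 rose, or 11 and 2 adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.0299, and adjusted p = 0.212 with an estimated correlation). Ddit4 fell by 1.13 ± 0.08, the folliculin gene Flcn by 0.71 ± 0.06 and Rraga by 0.53 ± 0.07. The list did not pass with the mean of all probe sets of a gene (adjusted p = 0.0511, range over its alternatives 0.000202 to 0.212). Tfeb, which encodes a master regulator of lysosomal genes, was at 6.88 in control and 6.92 in starved cells (0.04 ± 0.06), Mitf differed by 0.04 ± 0.08 and Rragd by -0.19 ± 0.07, none of them passing. Rragd passed without control replicate 3 (adjusted p = 0.0120) and with array weights (0.0370), with a range over its alternatives of 0.0120 to 0.183. Tfe3 was not analysed here.

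Every measured gene of cholesterol synthesis and its regulator SREBP2 fell, 19 of 19, with a median of -1.20 (camera adjusted p = 1.60e-14, and adjusted p = 0.212 with an estimated correlation). Besides Msmo1, Sqle and Idi1 the largest fall was in Mvd (-2.21 ± 0.09), and Hmgcs1, which makes the precursor of mevalonate, fell by 1.56 ± 0.06. Among fatty acid synthesis genes 9 of 19 fell and 3 rose, or 9 and 4 adjusted over the list alone, with a median of -0.12 and a mean of -0.38 (camera adjusted p = 0.0228, and adjusted p = 0.212 with an estimated correlation). Elovl6 fell by 1.80 ± 0.07, fatty acid synthase Fasn by 1.66 ± 0.08, Scd2 by 0.86 ± 0.06 and Acly by 0.86 ± 0.06. Genes of glycolysis and the hypoxia response fell in 20 of 27 and rose in 1, or 20 and 2 adjusted over the list alone, with a median of -0.60 (camera adjusted p = 2.00e-07, and adjusted p = 0.387 with an estimated correlation). Relative to each gene's mean over all arrays, the list's mean was 0.48, 0.39 and 0.22 in control replicates 1, 2 and 3 and -0.37, -0.39 and -0.33 in starved replicates 1, 2 and 3. Control replicate 3 also stood apart on the second principal component of all arrays (-14.6, against 8.78 and 5.16 in the other control arrays), which held 5.81% of the variance. The hexokinase gene Hk2 fell by 2.28 ± 0.08, the glucose transporter gene Slc2a1 by 1.79 ± 0.10 and the prolyl hydroxylase gene Egln1 by 1.48 ± 0.11, while Pkm differed by -0.04 ± 0.05 without passing. Fatty acid oxidation genes rose in 5 and fell in 3 of 23 (median 0.02, mean -0.01, camera direction higher, adjusted p = 0.925), with Pdk4 up by 0.71 ± 0.06 while the coactivator gene Ppargc1a fell by 0.73 ± 0.06. Oxidative phosphorylation genes rose in 3 and fell in 9 of 40, or 2 and 9 adjusted over the list alone (camera adjusted p = 0.439).

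Among stress responses, 20 of 42 genes of the ATF4 amino acid response rose and 9 fell, or 22 and 9 adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.0318, and adjusted p = 0.416 with an estimated correlation). Nupr1 rose by 1.35 ± 0.06, asparagine synthetase Asns by 1.00 ± 0.05 and Ddit3, which encodes CHOP, by 0.92 ± 0.06. Cth fell by 1.29 ± 0.08, and Atf4 itself differed by -0.05 ± 0.06 without passing. The list lost its call without dim probe sets (adjusted p = 0.0920), without probe sets that can match several transcripts (0.245) and with the mean of all probe sets of a gene (0.0511), with a range over its alternatives of 0.00138 to 0.416. Genes of endoplasmic reticulum chaperones and the unfolded protein response fell in 14 of 28 and rose in 1, with a median of -0.19 (camera adjusted p = 0.00839, and adjusted p = 0.212 with an estimated correlation). Sdf2l1 fell by 1.11 ± 0.07 and Manf by 0.72 ± 0.06. p53 target genes rose in 20 of 24 and fell in 2, with a median of 0.47 (camera adjusted p = 2.00e-07, and adjusted p = 0.212 with an estimated correlation). Pmaip1 rose by 1.70 ± 0.07, the cell cycle inhibitor gene Cdkn1a by 1.08 ± 0.05 and Perp by 1.03 ± 0.06. FoxO targets rose in 11 and fell in 3 of 30, or 12 and 3 adjusted over the list alone, with a median of 0.12 (camera adjusted p = 0.0127, and adjusted p = 0.212 with an estimated correlation). Txnip rose by 1.72 ± 0.05, Gadd45b by 1.64 ± 0.05 and the atrophy ligase gene Fbxo32 by 1.02 ± 0.07, while Klf15 fell by 1.03 ± 0.09. NRF2 targets rose in 9 and fell in 2 of 24 (camera adjusted p = 0.266), and heat shock genes rose in 6 and fell in 5 of 20, or 6 and 6 adjusted over the list alone (camera adjusted p = 0.925).

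All 34 measured mitosis genes rose, with a median of 1.44 (camera adjusted p = 3.05e-25, and adjusted p = 0.212 with an estimated correlation). The kinetochore motor gene Cenpe rose by 2.09 ± 0.07, Kif23 by 2.00 ± 0.08, the mitotic kinase gene Aurka by 1.82 ± 0.07 and Nusap1 by 1.79 ± 0.07. DNA replication and E2F genes rose in 27 of 37 and fell in 3, or 28 and 3 adjusted over the list alone, with a median of 0.48 (camera adjusted p = 1.06e-06, and adjusted p = 0.387 with an estimated correlation). The polymerase gene Pole rose by 1.30 ± 0.07 and Cdc45 by 0.97 ± 0.06. The members that fell were the G1/S cyclin genes Ccne2 (-1.48 ± 0.10) and Ccne1, which fell by 1.00 ± 0.08, and the origin licensing gene Cdc6 (-0.84 ± 0.06), the last of which was singled out after its value was seen. Genes of D cyclins and cell cycle inhibitors rose in 10 and fell in 9 of 25 (camera adjusted p = 0.624). Ccnd1 fell by 0.97 ± 0.06, Rbl1 rose by 1.02 ± 0.08 and Rb1 by 0.90 ± 0.07, and Cdkn1b differed by 0.12 ± 0.08 without passing while its dimmer probe set rose by 0.37 ± 0.08 and the mean of both passed (0.24, adjusted p = 0.0168, range over its alternatives 0.0168 to 0.618).

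**Figure D2:**
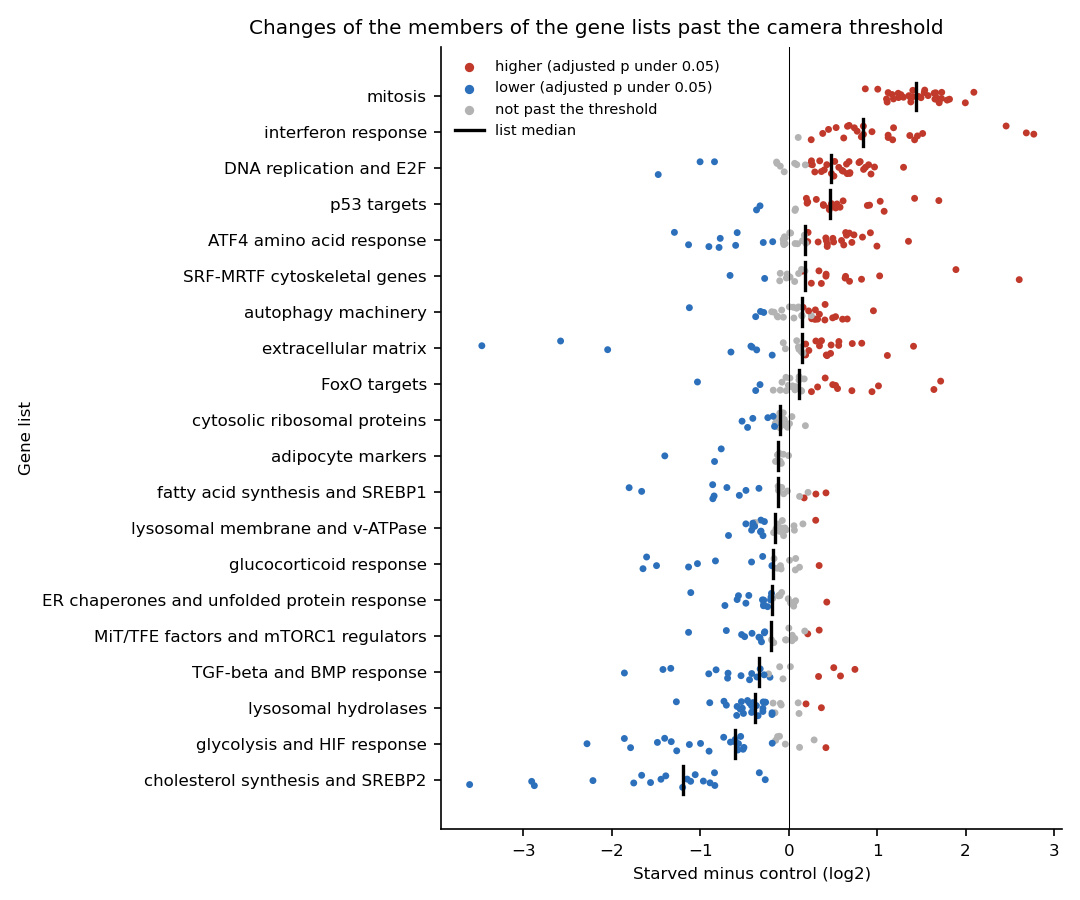
Change of each measured member (starved minus control, log2) of the 20 gene lists that passed camera with a preset correlation, with 1 point per gene, red for members called higher, blue for members called lower, grey for the rest and a black bar at the list's median. The medians run from -1.20 for cholesterol synthesis to 1.44 for mitosis.

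Interferon response genes rose in 24 of 25, with a median of 0.85 (camera adjusted p = 1.92e-11, and adjusted p = 0.301 with an estimated correlation). Relative to each gene's mean over all arrays, the mean of this list was uneven within both groups, at -0.51, -0.68 and -0.43 in control replicates 1, 2 and 3 and 0.41, 0.48 and 0.72 in starved replicates 1, 2 and 3. Besides Cxcl10, Rsad2 and Mx1, the transcription factor gene Irf7 rose by 1.52 ± 0.12. Ifitm3 differed by 0.11 ± 0.06 without passing. Beside this rise, leukocyte marker genes had a median level of 4.86 and a median change of -0.11, with 2 of 14 higher and 3 lower (camera adjusted p = 0.562). Genes of NF-kappaB signalling and inflammation rose in 11 and fell in 11 of 27, or 11 and 12 adjusted over the list alone (median 0.02, mean -0.01, camera direction lower, adjusted p = 0.925). The NF-kappaB subunit genes Relb (1.64 ± 0.06) and Nfkb2 (1.29 ± 0.06) rose, and the chemokine gene Cxcl5 (-1.77 ± 0.09) and the lipocalin gene Lcn2 (-1.65 ± 0.09) fell.

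Serum immediate early genes rose in 12 and fell in 14 of 39, or 12 and 15 adjusted over the list alone (camera adjusted p = 0.369). The growth factor signalling inhibitor genes Spred2 (-1.73 ± 0.07) and Spry2 (-1.50 ± 0.09) fell, as did Fos (-0.64 ± 0.08), while Gem rose by 1.52 ± 0.06 and Egr1 differed by -0.06 ± 0.08 without passing. Myc fell by 0.22 ± 0.06, a call lost without starved replicate 2 (adjusted p = 0.0553) or starved replicate 3 (0.0504), with a range over its alternatives of 0.00346 to 0.0553. Cytoskeletal genes controlled by SRF and MRTF rose in 13 and fell in 2 of 25, with a median of 0.18 (camera adjusted p = 0.00126, and adjusted p = 0.387 with an estimated correlation). Besides Actg2, Tagln rose by 1.89 ± 0.08 and Myl9 by 1.03 ± 0.07, and Actb differed by 0.07 ± 0.05 without passing. YAP-TEAD targets rose in 8 and fell in 4 of 21, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.0635), with Ankrd1 up by 1.48 ± 0.11. This list passed with an intensity trend (adjusted p = 0.0428, range over its alternatives 0.00199 to 0.517). Genes of the TGF-beta and BMP response fell in 14 of 22 and rose in 4, with a median of -0.34 (camera adjusted p = 0.00334, and adjusted p = 0.277 with an estimated correlation). Bhlhe40 fell by 1.86 ± 0.11, and the BMP targets Id1 and Id2 fell by 1.42 ± 0.07 and 1.33 ± 0.09. Glucocorticoid response genes fell in 9 of 18 and rose in 1 (median -0.18, camera adjusted p = 0.00439, and adjusted p = 0.212 with an estimated correlation), in which Errfi1 fell by 1.61 ± 0.06 and Cebpd fell by 1.49 ± 0.05.

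Extracellular matrix genes rose in 16 and fell in 8 of 34, or 20 and 8 adjusted over the list alone. Their median was 0.15 and their mean -0.02, since the metalloproteinase genes Mmp3 and Mmp13 and Lum (-2.05 ± 0.06) fell far while Tnc rose by 1.41 ± 0.11. Camera called the list higher (adjusted p = 0.0358, and adjusted p = 0.648 with an estimated correlation), but fry did not pass it (adjusted p = 0.437), and the call was lost without control replicate 2 (0.0638) or starved replicate 1 (0.0825). It was also lost without dim probe sets (0.0937) and without probe sets that can match several transcripts (0.102), with a range over its alternatives of 0.0124 to 0.648. Cytosolic ribosomal protein genes fell in 7 of 29 and rose in 0, or 4 and 0 adjusted over the list alone, with a median of -0.10 (camera adjusted p = 0.00929, and adjusted p = 0.359 with an estimated correlation). Rps6 fell by 0.53 ± 0.06, and the list did not pass after a second quantile normalization (adjusted p = 0.0580) or without probe sets that can match several transcripts (0.245), with a range over its alternatives of 0.000971 to 0.359. Ribosome biogenesis genes fell in 21 and rose in 9 of 42 (camera adjusted p = 0.0635), and Rrs1 fell by 1.05 ± 0.09. This list passed without control replicate 1 (adjusted p = 0.0381), control replicate 2 (0.0395), starved replicate 1 (0.0290) or starved replicate 3 (0.0161), after a second quantile normalization (0.0447) and with the mean of all probe sets of a gene (0.0116), with a range over its alternatives of 0.0110 to 0.649. Genes of purine, pyrimidine and one-carbon synthesis rose in 6 and fell in 5 of 17, or 8 and 5 adjusted over the list alone (camera adjusted p = 0.550). Circadian clock genes rose in 4 and fell in 8 of 17, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.550), and Cry1 fell by 1.19 ± 0.08 while Nr1d2 rose by 0.93 ± 0.05.

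**Figure D3:**
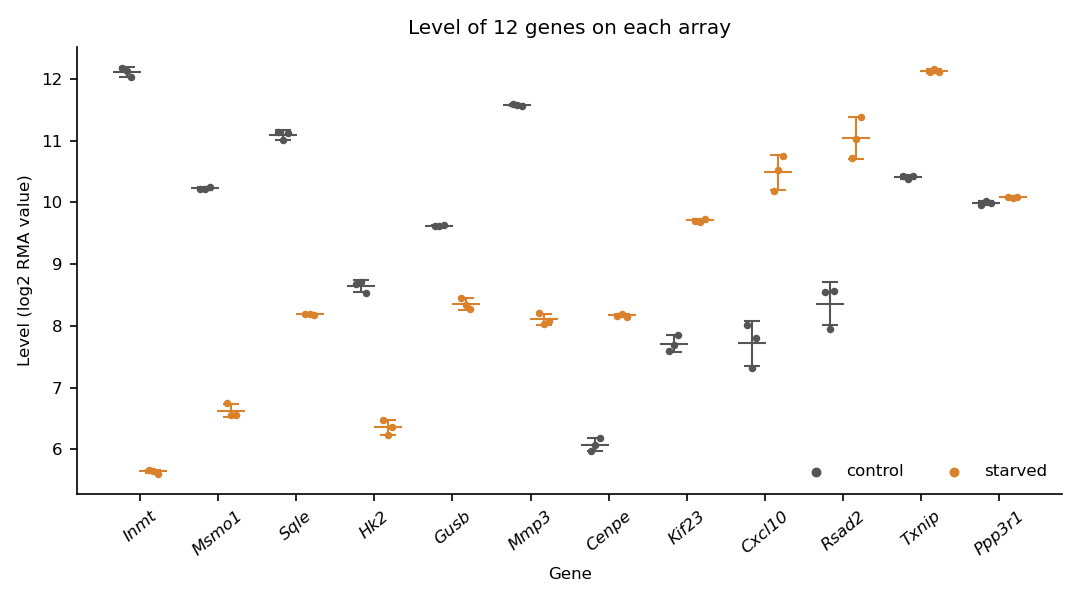
Level (log2 RMA value) of 12 genes on each array, with 1 point per array, grey for control and orange for starved, a horizontal line at the group mean and whiskers of 1 SD (n = 3). Inmt has means of 12.12 and 5.64, whereas Ppp3r1, with means of 9.99 and 10.08, did not pass the threshold.

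Fibroblast markers had a median level of 10.95, and 5 of 17 rose and 6 fell, or 7 and 6 adjusted over the list alone (median 0.06, mean -0.21, camera direction lower, adjusted p = 0.925). Within this list Fap fell by 2.26 ± 0.13 and Twist2 by 1.26 ± 0.06, Mfap5 rose by 1.33 ± 0.06, and Col1a2 differed by 0.14 ± 0.05 without passing. Col1a2 passed with the mean of its probe sets (0.31, adjusted p = 0.00119, range over its alternatives 0.000143 to 0.148). Markers of other cell types lay mostly near background. Their median levels were 4.42 for epithelial, 4.35 for endothelial, 4.14 for muscle, 4.96 for neural and glial and 4.41 for pluripotency and embryonal markers, and none of these lists passed (camera adjusted p from 0.562 to 0.930). Epithelial markers rose in 1 and fell in 0 of 14, and neural and glial markers rose in 2 and fell in 1 of 15. Endothelial markers rose in 2 and fell in 1 of 12, or 1 and 0 adjusted over the list alone. Muscle markers rose in 2 and fell in 0 of 17, or 0 and 0 adjusted over the list alone, and pluripotency markers rose in 1 and fell in 1 of 11, or 1 and 0 adjusted over the list alone. The pluripotency list had a median of -0.07 and a mean of 0.05, with camera lower and fry higher. Adipocyte markers, at a median level of 6.04, fell in 3 and rose in 0 of 10 (median -0.12, camera adjusted p = 0.0317, and adjusted p = 0.220 with an estimated correlation). Plin4 fell by 0.84 ± 0.06 and Cebpa by 0.76 ± 0.11, and the list lost its call without probe sets that can match several transcripts (adjusted p = 0.115, range over its alternatives 3.70e-05 to 0.220).

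RNA quality was compared through the control probe sets of Gapdh and Actb, in which the groups did not overlap for Gapdh. The log2 difference between the 3 prime and 5 prime control probe sets was -0.05 ± 0.05 (SD, n = 3) in control and -0.13 ± 0.02 (SD, n = 3) in starved samples for Gapdh (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 arrays allow). For Actb it was 0.05 ± 0.02 in both groups (exact permutation test, two-sided, p = 0.7). The spiked hybridization controls were higher by 0.14 and the spiked polyadenylated controls lower by 0.11 on average in the starved arrays, and the groups did not overlap in either average.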

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

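The fit of the control probe sets was not among the tests fixed in advance. Control probe sets of the array were outside the comparison, and of 64 of them 6 were higher and 9 lower in starved than in control arrays at limma's adjusted p of 0.05, in a separate fit of the control probe sets. Those for the mouse repeats B1 and B2, short interspersed elements that lie in many transcripts, were higher by 0.34 (AFFX-MURINE_B2), 0.23 (AFFX-MUR_b2) and 0.19 (AFFX-MURINE_b1). The other 3 higher ones measure RNA spiked into the samples: AFFX-r2-Ec-bioB-5 was higher by 0.25, AFFX-r2-P1-cre-5 by 0.18 and AFFX-CreX-3 by 0.16. Of the 9 lower ones, the 4 for pyruvate carboxylase (AFFX-PyruCarbMur) changed by -0.66 to -0.35, and the 3 for the transferrin receptor (AFFX-TransRecMur), all with means under 5, by -0.32 to -0.26. The spike AFFX-r2-Bs-phe-3 changed by -0.22 and AFFX-TrpnX-5 by -0.19. No explanation was tested for these changes.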

How the results depend on the processing

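No alternative in this part was chosen after its result was seen. No list past camera reversed, and of 127 genes named Ppp3cb alone did: the mean of its probe sets was higher by 0.20. Leaving out probe sets that can match several transcripts gave 5716 probe sets (2888 higher, 2828 lower), with fewer tested. A minimum change of 1 gave 689 probe sets (354 higher, 335 lower) and 398 genes (212 higher, 186 lower), by its construction. Under all other alternatives the counts of probe sets and genes stayed within 1.5 times, from 7673 probe sets without moderation (6252 at a threshold of 0.01) to 9745 with an intensity trend. Leaving out 1 array gave 7691 to 8394 probe sets and 4384 to 4757 genes. The number of lists past camera fell from 20 to 0 with an estimated correlation and was 28 with fry; it was 14 without probe sets that can match several transcripts, 17 without dim ones and 19 to 21 when an array was left out. With an intensity trend Actb, Col1a2, Ctsl, Ifitm3 and Lamp1 also passed, and without moderation Actb, Col1a2 and Ppp3r1. For Gapdh the 3 prime to 5 prime difference between groups of -0.08 was -0.023 against the middle probe set; the cause was not tested. No pairing by replicate number was visible: deviations of same-numbered arrays correlated at -0.09, 0.01 and -0.01, and those of other pairs at -0.08 to 0.09. With 3 arrays per group this does not show that same-numbered samples were handled apart. With the replicate block 8168 probe sets, 4624 genes and 20 lists passed. Signal over background limits the 3509 genes with both means under 5, of which 231 were called.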

Other observations

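The gene families and the genes named in this paragraph and the next were chosen after the data were seen. Genes were grouped by the stem of their symbol, and 5 of 204 families with at least 10 members passed camera with a preset correlation, 0 with an estimated one (adjusted p = 0.992 for each of the 5, with 4 families at an unadjusted p under 0.05). Centromere protein genes (Cenp) rose in 11 and fell in 2 of 14, with a median of 0.62 (adjusted p = 0.00216), and kinesin genes (Kif) rose in 13 and fell in 1 of 28 (median 0.20, adjusted p = 0.0260). Both overlap with the mitosis list. Proteasome genes (Psm) rose in 19 and fell in 5 of 48 (median 0.14, adjusted p = 0.0269), led by the immunoproteasome subunit genes Psmb8 (1.18 ± 0.10), Psmb9 (1.12 ± 0.09) and Psmb10 (0.82 ± 0.09). Protocadherin genes with a single letter between Pcdh and the number of the symbol (Pcdh) fell in 10 of 22 (median -0.25, adjusted p = 0.0260). Both means lay under 5 in 14 of the 22, and other protocadherin genes had other stems. Genes of the TRAPP vesicle tethering complex (Trapp) fell in 7 of 10 (median -0.24, adjusted p = 0.0355). The sign of each median was the same after a second quantile normalization and after centring.

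The classical MHC class I genes H2-K1 (1.19 ± 0.06) and H2-D1 (1.18 ± 0.06) rose in limma's test, in probe sets that can match related transcripts. Of 9 SR splicing factor genes 7 fell and 2 rose, with the largest falls in Srsf2 (-1.38 ± 0.06), Srsf6 (-1.28 ± 0.06) and Srsf3 (-0.90 ± 0.07), but the Srsf2 call rests on 3 probe sets that can match several transcripts. Without such probe sets Srsf2 did not pass (-0.06 ± 0.09, adjusted p = 0.667, range over its alternatives 1.83e-13 to 0.667). 1 probe set of Srsf3 was called in the opposite direction.

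Of the tests below, those of the replication and endomembrane lists and of the spiked controls were chosen after the result was seen. 10 splits of 6 arrays into 3 and 3 are too few to reach a share under 0.05. Of them 1, the real one, called as many as 8933 probe sets, and the highest of the others called 0 in limma (616 at most at an unadjusted p under 0.05, against 10575). Each of the others mixes starved and control arrays, so the difference between the groups enters its spread and lowers its calls. Their counts therefore do not show what would be called without a difference between groups.

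Mitosis genes rose in starved cells by a median of 1.44. Of 10000 random lists of the same size and level the highest median was 0.30, and the largest change of any of 21 spiked control probe sets was 0.25, which argues against a shift by signal level, labelling or hybridization as the whole cause. A larger share of cycling cells with no shift in phase remains open. The replication list rose too, by 0.95 less than the mitosis list (permutation test of members, p = 1e-05, the smallest it can give). Within the replication list 27 of 37 genes rose and 3 fell, led by Ccne2 (-1.48) with Ccne1 and Cdc6. A shift of cells between phases of the cycle was not tested and stays open. Separate handling of the cultures of each group cannot be excluded either, nor can control arrays from another line, which the growth and treatment protocols name.

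Lysosomal hydrolase genes fell by a median of 0.38 on the log2 scale while most autophagy genes called rose. The autophagy list lost its camera call under some alternatives, as given above. For the hydrolases the lowest median of 10000 level-matched random lists was -0.33, which argues against a shift by signal level alone. The autophagy median of 0.15 lay under the highest of its own matched lists, 0.31, so a random draw of genes at that level could also give it. The matched lists themselves had a median of 0.02, which argues against a shift of genes of this level as a group. Of the other lists past camera, those of mitosis, cholesterol synthesis, glycolysis, p53 targets, replication and interferon lay outside the range of their matched lists. The rest lay within it, but the most extreme of 10000 lists set this range, so lying within it does not make a list like random ones. The TGF-beta median of -0.341 lay close to the lowest of its matched lists, -0.343. FoxO targets, at 0.12 against a highest of 0.29, lay further inside. The hydrolase median lay below that of the endoplasmic reticulum chaperone list by a difference of -0.19 (permutation test of members, p = 0.0187) and below that of the lysosomal membrane list by -0.22 (p = 0.00681), which argues against an equal fall across the endomembrane system, though genes are not independent. No other line was starved here, so whether the fall depends on the state of calcineurin in this line was not tested. Control arrays from another line cannot be excluded for this fall either.

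Inmt fell most, and the loss of 6.47 within 6 h would need a transcript half-life of at most 55.6 min with no new synthesis, against 99.8 min for Msmo1. Since the growth and treatment protocols name another control, control arrays from another line are a candidate explanation. Of 19 homeobox cluster (Hox) genes at a level of 5 or more, 11 were called but 0 differed by at least 1 (largest 0.89). Both counts lie near the shares of all genes: 398 of 12393 (3.21%) changed by at least 1, and 5350 of 8885 passed without dim probe sets. Lines from similar embryos could also share these levels, so the counts do not decide and the explanation stays open. A fault of the single Inmt probe set was not tested and stays open, since values of other genes (all probe sets fell in 6 of 8 with several probe sets and a fall of at least 2) say nothing of that probe set. Starvation, mislabelled controls and culture handling cannot be told apart for Inmt.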
